A study of Homo sapiens with 8 samples.

How the data were processed

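Poly-A RNA from SW480 and SW620 cells, with caffeine or untreated, was sequenced in 8 libraries, 2 per line and treatment. Per the labels, the RNA had an integrity number of at least 8, libraries were made with a directional poly-A kit (NEBNext Ultra II) and single-end reads of 75 bp came from a NextSeq 500. The labels describe caffeine at 30 to 500 µM for 72 hours and at 125 µM for 28 days in SW620 cultures, and do not say which dose or time the sequenced libraries had. The authors deposited 1 file of counts per library, that is raw reads per Ensembl gene, and named Trim Galore (no version), STAR 2.7.3a, featureCounts 2.0.5 and the hg38 genome. The strand setting, the annotation release and whether replicates were separate cultures on 1 day or several were not given in the sources used here.

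Each file held 62649 genes and 12 assignment totals, which were left out, and the sum over genes equalled the file's own total of assigned reads. Of the gene IDs 62625 were matched to gene symbols and 58225 to GENCODE 29, from which GRCh38 coordinates and exon overlaps were taken. Library totals ran from 15760259 to 23269315 assigned reads. A count of 0 allows up to 3 counts at 95%, which was used as the floor over a group, and folds against a group at 0 are given as lower bounds. These bounds take the count of the other group as exact, so that they are no 95% limits where that count is small. Of 35897 genes with any count, 17671 passed edgeR's filterByExpr and were tested, and they held at least 99.8597% of the assigned reads of each library.

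Tests used edgeR 4.0.16 in R 4.3.3 (TMM scaling, robust quasi-likelihood fit and F test, Benjamini-Hochberg adjustment over all tested genes, threshold 0.05) with all 8 libraries in 1 fit and a mean for each of the 4 groups. The contrasts were caffeine against control in SW480 and in SW620, the difference of these effects (SW620 minus SW480) and the SW620 against the SW480 controls. A response over both lines was fitted with line and treatment as additive terms. With 2 libraries per group the groups share 1 estimate of the spread, and the biological coefficient of variation was 10.5% over all libraries, 13.1% in SW480 and 7.02% in SW620. No block was used, since nothing in the labels says that a replicate number marks a shared batch or day. Within a line, the correlation of same-numbered deviations was 0.0265 in SW480 and 0.0134 in SW620, which does not test a block shared by the lines. Levels are CPM after TMM scaling, and log2 CPM for the principal components used a prior count of 2.

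Gene lists were tested with camera in limma 3.58.1 against the other tested genes, with a preset inter-gene correlation of 0.01, at least 3 tested members and adjustment over the lists of a comparison. The 35 lists were immunoproteasome subunits, immunoproteasome assembly and MHC class I presentation, constitutive 20S proteasome, 19S and other proteasome regulators, interferon-stimulated genes, cAMP and CREB targets, phosphodiesterases, adenosine receptors and handling, calcium channels and pumps, aryl hydrocarbon receptor targets, NRF2 targets, p53 targets, G2/M and mitosis, and DNA replication and S phase. Others were ATM and ATR checkpoint and repair, ATF4 and amino acid response, unfolded protein response, heat shock, cholesterol synthesis and uptake, fatty acid synthesis, glycolysis and hypoxia, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, and replication-dependent histones. The rest were NF-kB and inflammatory cytokines, Wnt targets, autophagy and lysosome, epithelial adhesion, mesenchymal and invasion genes, intestinal differentiation, apoptosis regulators, and fibroblast, leukocyte and endothelial markers. Within a list, genes were also adjusted over that list alone.

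The comparisons, the lists, the naming rule and the alternatives were set before the data were examined, apart from those said to have been chosen later. Per comparison the rule named the 10 largest changes in each direction (5 for the difference between lines) among called genes with a mean log2 CPM of at least 1 and no overlap between the libraries of the 2 sides, the catalytic proteasome subunits, and up to 4 members of each list by adjusted p. Genes outside the rule were named after their values were seen, because a count of 5 or fewer or an exception called for the name. The results of 2 list members are not reported here. Of 328 named genes, 327 were in GENCODE 29, 133 shared exon bases with another gene and 43 did so on the same strand.

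The alternatives were DESeq2 size factors in the edgeR fit, no filter on low counts, the Wald test of DESeq2 1.42.0, limma-voom, and the replicate number as a block. Further ones were a separate fit of each line, the average of the lines' contrasts, each library left out in turn, and for lists an estimated inter-gene correlation and fry. A fit without the mitochondrial genes was added after the data were seen. Medians had bootstrap intervals from 10000 resamples at 95%. The pipeline was tested on simulated data with changes of 0.5, 1 and 2 on the log2 scale. Of these edgeR recovered 13.4%, 65.7% and 84.8% in SW480, 19.4%, 76.1% and 81.8% in SW620, and 4.48%, 44.8% and 71.2% for the difference between lines. False calls made up 6.84%, 6.35% and 6.98% of its calls in the same order. All simulated libraries had the spread estimated over all 8 libraries, so that these shares leave out the unequal spread of the lines. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.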

Results

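Poly-A RNA was sequenced from SW480 and SW620, human colorectal adenocarcinoma cell lines derived from a primary tumour and a lymph node metastasis of the same patient, with and without caffeine, a methylxanthine that blocks adenosine receptors. Per the labels, both lines carried a fluorescent PSMB8-mCherry (B8-mCherry) immunoproteasome fusion, and the immunoproteasome is named in the title of the series. The 8 libraries formed 4 groups of 2: SW480 control, SW480 caffeine, SW620 control and SW620 caffeine. The labels did not state the caffeine dose or the exposure time of the sequenced libraries. Reads assigned to genes numbered 16433958 and 17534930 in the SW480 control libraries (replicates 1 and 2), 15760259 and 23269315 in the SW480 caffeine libraries, 19599618 and 19758170 in the SW620 control libraries, and 16824768 and 19942730 in the SW620 caffeine libraries. At these depths 3 counts, the upper limit that a count of 0 allows, corresponded to 0.129 to 0.190 CPM (counts scaled by the library total) per library. The lines lay apart on the first principal component, which held 89.4% of the variance, and the caffeine and control libraries of SW620 lay apart on the second, with 3.62%. In SW480 caffeine replicate 2, 1.63% of assigned reads fell on mitochondrial genes, against 4.38% to 6.16% in the other 7 libraries.

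The first question was whether caffeine changed the transcripts of the 3 catalytic immunosubunits, which replace PSMB6, PSMB7 and PSMB5 in the immunoproteasome, the proteasome form that generates peptides for MHC class I. In SW620, PSMB9 fell from 7.73 ± 0.41 to 3.42 ± 0.21 CPM (mean ± SD, n = 2 per group). In the same line PSMB8 stood at 34.7 ± 1.91 CPM without and 25.1 ± 1.47 with caffeine, and PSMB10 at 10.1 ± 1.39 and 8.57 ± 1.52 CPM, and neither passed the test over all genes. In SW480 none of the 3 was called: PSMB8 measured 30.2 ± 7.68 CPM without and 25.8 ± 3.20 with caffeine, PSMB9 11.6 ± 0.757 and 14.4 ± 0.708, and PSMB10 5.37 ± 0.746 and 5.05 ± 1.78. The PSMB9 response differed between the lines, by a log2 value of -1.49 ± 0.24 (SE, SW620 minus SW480, adjusted p = 0.00133).

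By edgeR's quasi-likelihood test, the log2 fold changes in SW620 were -1.17 ± 0.18 (SE) for PSMB9 (adjusted p = 0.000456), -0.47 ± 0.16 for PSMB8 (adjusted p = 0.0666) and -0.24 ± 0.22 for PSMB10 (adjusted p = 0.509). In SW480 they were 0.32 ± 0.16 for PSMB9 (adjusted p = 0.272), -0.23 ± 0.16 for PSMB8 (adjusted p = 0.482) and -0.12 ± 0.25 for PSMB10 (adjusted p = 0.834). The 3-gene list of immunosubunits was lower in SW620, with a median log2 fold change of -0.47 and a camera adjusted p of 0.0274, where 1 gene fell and 2 fell adjusted over the list alone (PSMB8 and PSMB9). With an estimated correlation this list's adjusted p was 0.242, and without SW620 caffeine replicate 2 its adjusted p with the preset correlation was 0.0582. In SW480 the list was not called (median -0.12, adjusted p = 0.934), and the list's own difference between the lines missed the threshold (adjusted p = 0.0517). The constitutive catalytic subunits were not called in either line. In SW480, PSMB5 had a log2 fold change of 0.25, PSMB6 of 0.04 and PSMB7 of -0.08, and in SW620 -0.23, -0.03 and 0.07. PSMB8 in SW620 passed the threshold with the replicate number as a block (adjusted p = 0.0303), in a separate fit of that line (0.00398) and with no filter on low counts (0.0388). It also did so without SW480 control replicate 1 (adjusted p = 0.0171) or without SW480 control replicate 2 (adjusted p = 0.0214), and the sign of PSMB8 in SW480 turned without SW480 control replicate 2 (0.05). PSMB8 counts cannot be divided between the resident gene and the fusion.

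On GRCh38, PSMB8 lies on chromosome 6 from 32840717 to 32844703, PSMB9 on chromosome 6 from 32844136 to 32859585, and PSMB10 on chromosome 16 from 67934502 to 67937087. Annotated exons of PSMB9 share 139 bases with PSMB8 on the opposite strand and 174 bases with PSMB8-AS1 on the same strand, those of PSMB8 share 618 bases with PSMB8-AS1 on the opposite strand, and those of PSMB10 share 644 bases with AC040162.1 on the same strand. How reads in bases shared on opposite strands were counted depends on a strand setting that the labels did not give. No strand setting separates genes that share bases on the same strand, so that PSMB10 and PSMB9 counts may leave out such reads.

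**Figure D1:**
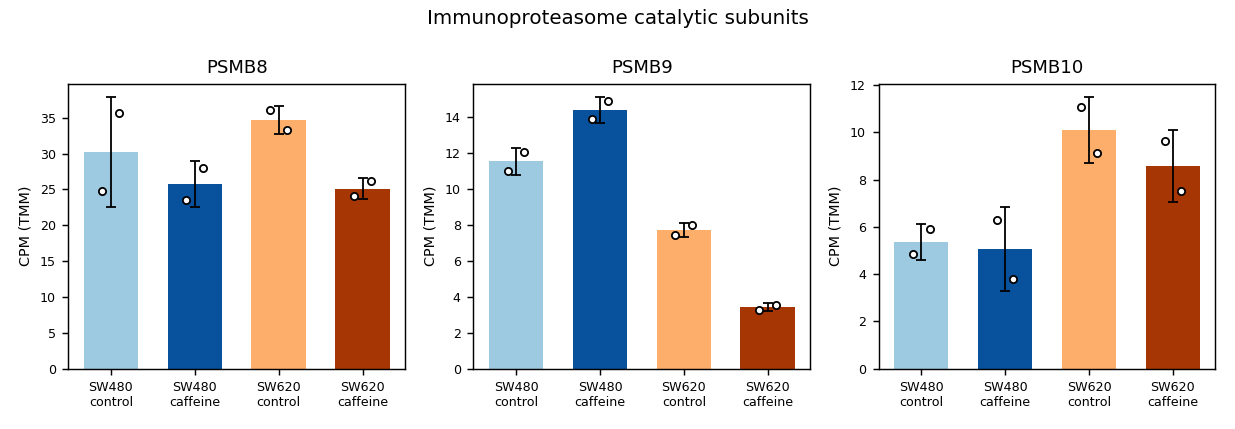
Expression of PSMB8, PSMB9 and PSMB10 in CPM after TMM scaling (linear axis from 0); bars are means of 2 libraries, error bars are SD and points are single libraries. PSMB9 fell in SW620 from 7.73 to 3.42 CPM, and no other caffeine difference shown here passed the test over all genes.

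In SW480, caffeine raised genes of the amino acid stress response and some histone genes and lowered the death ligand TNFSF10 and the lipid carrier APOE. The lists of both groups lost their calls with an estimated correlation (adjusted p = 0.364 each). CHAC1, a glutathione-degrading enzyme, rose from 6.25 ± 1.48 to 16.3 ± 0.486 CPM (mean ± SD, n = 2), and INHBE, which encodes an inhibin subunit, from 4.93 ± 0.463 to 15.3 ± 0.673 CPM. CPLX2, a regulator of vesicle release, rose from 7.55 ± 0.0240 to 25.3 ± 1.45 CPM and HES5, a Notch target, from 6.22 ± 1.44 to 17.8 ± 0.101 CPM. TNFSF10 fell from 8.11 ± 0.172 to 1.98 ± 0.933 CPM and APOE from 37.4 ± 5.69 to 11.9 ± 2.40 CPM. The antisense RNA IGFL2-AS1 fell from 199.5 ± 26.3 to 51.1 ± 9.10 CPM, and the adjacent pseudogene IGFL1P1 from 13.8 ± 3.04 to 3.75 ± 0.247 CPM.

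Of 17671 genes tested in SW480, 636 were called by edgeR, 295 higher and 341 lower with caffeine, and 209 of them changed by a log2 value above 1 in size. The largest rises that met the rule for named genes included CPLX2 (log2 fold change 1.74 ± 0.16, SE, adjusted p = 2.41e-05), INHBE (1.63 ± 0.17, 9.56e-05), SPNS2, a lipid transporter (1.54 ± 0.16, 9.52e-05), PSD2 (1.54 ± 0.16, 0.000114), HES5 (1.51 ± 0.20, 0.000802) and CHAC1 (1.38 ± 0.17, 0.000416). The largest falls included TNFSF10 (-2.10 ± 0.24, 0.000198), IGFL2-AS1 (-1.97 ± 0.16, 1.95e-05), IGFL1P1 (-1.88 ± 0.22, 0.000251) and APOE (-1.64 ± 0.18, 0.000114). These 10 kept their calls when any 1 library was left out. The other 10 of the 20 largest changes, namely TFF3, TXNDC5, IDNK, LINC01238, GRIN2B, SHANK1, IFIT2, IFITM1, REPIN1-AS1 and ENDOU, lost them without SW480 caffeine replicate 2, with adjusted p from 0.0831 to 0.447. Of these, 8 also did so without SW480 control replicate 1 (0.0535 to 0.326), 3 without SW480 control replicate 2 (TFF3, LINC01238 and IFITM1, 0.0739 to 0.140), GRIN2B without SW480 caffeine replicate 1 (0.0640), and TFF3 and IFITM1 without SW620 control replicate 1 or 2 (0.0565 to 0.132). IFITM1 also did so without SW620 caffeine replicate 1 or 2 (0.133 each). TFF3 rested on 2 counts in the control and 20 in the caffeine libraries, a ratio of 8.70 with a 95% counting interval from 2.11 to 76.8. The count of calls was 50 without SW480 caffeine replicate 2, 180 without SW480 control replicate 1, 370 and 381 without SW620 control replicate 1 or 2, 1052 without SW480 caffeine replicate 1 and 1367 without SW480 control replicate 2.

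Among the lists fixed in advance, the ATF4 and amino acid response list, whose genes supply amino acids and respond to their shortage, had the smallest camera adjusted p in SW480 with the preset correlation. Of its 30 tested genes 11 rose and none fell (21 and 0 adjusted over the list alone), with CHAC1, DDIT4 (log2 fold change 0.90 ± 0.12, SE) and SESN2 (1.01 ± 0.14) among them, the latter pair inhibitors of mTORC1 signalling. The list's median was 0.45 and its camera adjusted p 4.39e-17, and its adjusted p with an estimated correlation was 0.364. Of 21 replication-dependent histone genes 5 rose and none fell, also adjusted over the list alone, with H2BC12 (1.18 ± 0.14), H2AC6 (1.16 ± 0.15) and H2BC11 (1.01 ± 0.20) as examples. The histone median was 0.73 with adjusted p = 2.75e-05, and 0.364 with an estimated correlation. H1-2 (1.02 ± 0.19) and, named after its values were seen, H4C8 (1.16 ± 0.29) were the others. Without SW480 control replicate 1 the adjusted p was 0.101 for H2BC11, 0.0576 for H1-2 and 0.0900 for H4C8, and without SW480 caffeine replicate 2 it was 0.0521 for H1-2 and 0.259 for H4C8. H4C8 also lost its call without SW480 control replicate 2 (0.105) and without SW620 control replicate 1 or 2 (0.0517 and 0.0515). The DNA replication and S phase list had 4 of 34 genes up and none down (5 and 0 adjusted over the list alone), with a median of 0.24 and adjusted p = 2.01e-06, and 0.502 with an estimated correlation. Its risers were TYMS (0.65), RRM2 (0.50), GINS2 (0.66) and LIG1 (0.51), which make nucleotides or act at replication forks. Each lost its call without SW480 caffeine replicate 2 (adjusted p = 0.172, 0.244, 0.259 and 0.448) and without SW480 control replicate 1 (0.110, 0.167, 0.210 and 0.161). GINS2 also lost it without SW480 caffeine replicate 1 (0.0550). RRM2 lost it without SW620 control replicate 1 or 2 (0.0677 and 0.0676), and LIG1 without any 1 of the 4 SW620 libraries (0.0615 to 0.0878). The autophagy and lysosome list had 3 of 29 genes down and none up (9 down and 1 up adjusted over the list alone), with a median of -0.16 and adjusted p = 0.00115, and 0.364 with an estimated correlation. RRAGD (-0.72 ± 0.12), a Rag GTPase of nutrient sensing, and the lysosomal membrane protein LAMP2 (-0.53) were among the fallers and lost their calls without SW480 caffeine replicate 2 (adjusted p = 0.0846 and 0.377). LAMP2 also did so without SW480 control replicate 1 (0.201) or any 1 of the SW620 libraries (0.0544 to 0.0741).

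Of the 35 lists, 7 more were called in SW480, and each lost its call with an estimated correlation. The 13 mitochondrially encoded mRNAs had a median of -0.75 (adjusted p = 0.00132, and 0.580 with an estimated correlation) although no gene was called and 1 fell adjusted over the list alone. This list moved with SW480 caffeine replicate 2, whose mitochondrial share was 1.63%: without that library the median was -0.14 (adjusted p = 0.0238), and without SW480 caffeine replicate 1 it was -1.84. Without SW480 control replicate 1 its adjusted p was 0.0557. G2/M and mitosis had a median of 0.16 with 0 of 30 genes called, also adjusted over the list alone (adjusted p = 0.00137, and 0.364 with an estimated correlation), and 0.0580 without SW480 caffeine replicate 1. Cholesterol synthesis and uptake had a median of 0.15 with 0 of 25 called and 4 up adjusted over the list alone (adjusted p = 0.0135, and 0.580 with an estimated correlation), which became 0.454 without SW480 control replicate 1 and 0.229 without SW480 caffeine replicate 2. ATM and ATR checkpoint and DNA repair had 1 of 25 up, and 3 adjusted over the list alone (median 0.19, adjusted p = 0.0171, and 0.553 with an estimated correlation), which became 0.198 without SW480 control replicate 2 and 0.0724 without SW480 caffeine replicate 1.

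The other 3 called lists had negative medians in SW480. Of 22 cAMP and CREB targets none was called and 6 fell with 1 up adjusted over the list alone, with a median of -0.30, or -0.26 with 1 gene at its bound (adjusted p = 0.0253, and 0.364 with an estimated correlation). Without SW480 control replicate 1, SW480 caffeine replicate 1 or SW480 caffeine replicate 2 its adjusted p was 0.0557, 0.0580 and 0.0748. Of 37 interferon-stimulated genes 1 rose and 5 fell (2 and 7 adjusted over the list alone), with a median of -0.16 (adjusted p = 0.0340, and 0.502 with an estimated correlation). The antiviral genes OAS1 (-0.80 ± 0.17, SE) and OAS2 (-0.86 ± 0.18) fell with IFIT2, IFITM1 and IFIT3 (-0.94 ± 0.25), and the exonuclease ISG20 rose (0.79 ± 0.20), the last pair named after their values were seen. OAS1, OAS2 and IFIT3 had adjusted p of 0.275, 0.213 and 0.348 without SW480 caffeine replicate 2, and OAS2 and IFIT3 0.119 and 0.170 without SW480 control replicate 1. IFIT3 also lost its call without SW480 caffeine replicate 1 (0.0821) or SW620 control replicate 1 or 2 (0.0621 and 0.0625), and ISG20 without any 1 of the 8 libraries (0.0514 to 0.175). That list lost its call with no filter on low counts (adjusted p = 0.120), without SW480 control replicate 2 (0.176) and without SW480 caffeine replicate 2 (0.156). Of 15 intestinal differentiation genes 2 rose and 3 fell (2 and 5 adjusted over the list alone), with a median of -0.14, or -0.13 with 3 genes at their bound, and a mean of 0.10, which differs in sign (adjusted p = 0.0455, and 0.364 with an estimated correlation). The mucin MUC13 (-1.48 ± 0.20) and the adhesion molecule CEACAM1 (-1.44 ± 0.20) were among those that fell, and TFF3 and ALPI, an intestinal alkaline phosphatase (1.15 ± 0.21), rose. Without SW480 caffeine replicate 2 the adjusted p was 0.0528 for MUC13, 0.0522 for CEACAM1 and 0.154 for ALPI, and without SW480 control replicate 1 it was 0.0523 for ALPI. The list kept its call only without SW480 control replicate 2, with adjusted p from 0.0774 to 0.124 without any other library, and lost it with DESeq2 size factors (0.0524) and with no filter (0.161).

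In SW620, caffeine raised glycolytic and hypoxia-inducible genes, mitotic genes, histone genes and inflammatory genes together. NDRG1, a hypoxia-inducible gene, rose from 8.36 ± 0.770 to 83.8 ± 1.07 CPM (mean ± SD, n = 2), and AKAP12, a kinase scaffold, from 71.7 ± 0.243 to 746.0 ± 12.1 CPM. The transcription cofactor LBH rose from 1.28 ± 0.0444 to 26.9 ± 3.57 CPM, the membrane protein EMP1 from 7.28 ± 0.484 to 76.4 ± 11.4 CPM, and the EGF receptor ligand EREG from 3.45 ± 1.01 to 33.8 ± 0.494 CPM. NUPR1, a stress-induced chromatin protein, fell from 11.1 ± 0.173 to 2.02 ± 0.0853 CPM. GPX8, an endoplasmic reticulum peroxidase, fell from 5.06 ± 0.499 to 1.22 ± 0.203 CPM and AVPR2, the vasopressin receptor, from 5.84 ± 0.111 to 1.47 ± 0.0575 CPM.

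Of the 17671 genes tested in SW620, edgeR called 2537, with 1432 higher and 1105 lower with caffeine, and 725 of them changed by a log2 value above 1 in size. Large rises included LBH (log2 fold change 4.38 ± 0.19, SE, adjusted p = 4.11e-10), EMP1 (3.39 ± 0.19, 1.20e-08), AKAP12 (3.38 ± 0.15, 4.11e-10), NDRG1 (3.32 ± 0.16, 1.15e-09), H2BC11 (3.31 ± 0.20, 2.99e-08), EREG (3.29 ± 0.20, 7.40e-08), H2BC4 (3.00 ± 0.31, 7.88e-06) and the phosphatase PTPRH (2.90 ± 0.24, 6.17e-07). Large falls included INTS4P1 (-3.03 ± 0.30, 7.86e-06), NUPR1 (-2.46 ± 0.23, 3.41e-06), LINC01594 (-2.26 ± 0.29, 7.47e-05), CTHRC1 (-2.05 ± 0.31, 0.000286), GPX8 (-2.04 ± 0.24, 2.48e-05) and AVPR2 (-1.98 ± 0.28, 0.000200). These 14 kept their calls when any 1 library was left out. KCNJ10 was at least 3.57-fold higher and COL13A1 at least 2.85-fold higher, EDN3 at least 2.49-fold lower and TSPAN7 at least 2.18-fold lower, each with 0 counts in a group and a floor of 3 counts over that group. These bounds take the counts of the other group, from 7 to 10, as exact, and the counts allow smaller folds. SIM2 had a ratio of 0.189 (counting interval 0.0355 to 0.653), and NELL2 fell from 32 to 7 counts. These 6 lost their calls without SW620 control replicate 1 (adjusted p from 0.0841 to 0.199), and subsets of them without SW620 control replicate 2 (0.0883 to 0.226), SW620 caffeine replicate 1 (0.0676 to 0.169) or SW620 caffeine replicate 2 (0.0620 to 0.195). TSPAN7 also did so without SW480 caffeine replicate 1 or 2 (0.0533 and 0.0530). The count of calls was 874 and 787 without SW620 control replicate 1 or 2, and 1362 and 1157 without SW620 caffeine replicate 1 or 2.

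**Figure D2:**
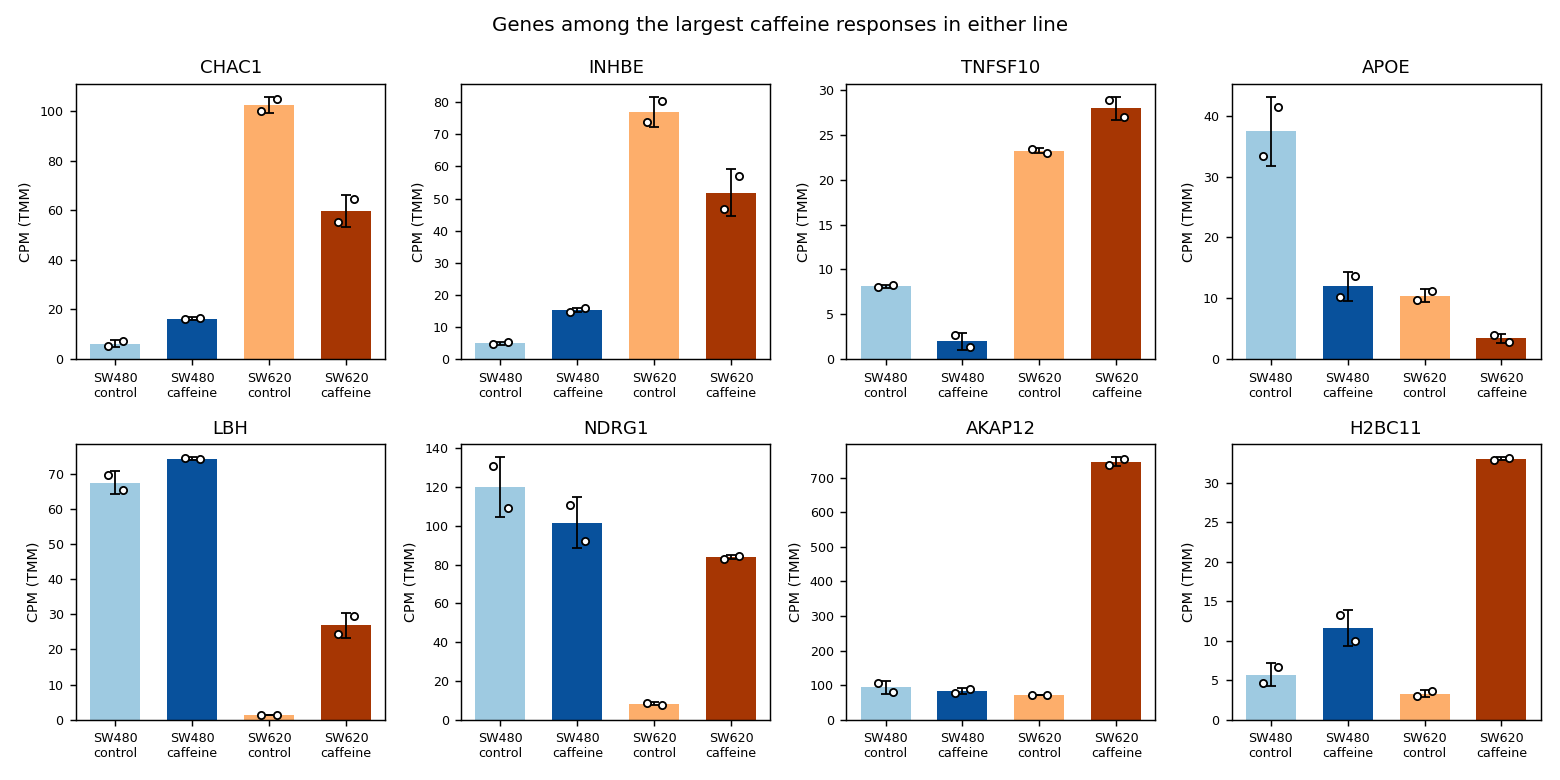
Expression of 8 genes among the largest caffeine responses, in CPM after TMM scaling (linear axes from 0); bars are means of 2 libraries, error bars are SD and points are single libraries. CHAC1 and INHBE were higher with caffeine in SW480 and lower in SW620, APOE was lower with caffeine in both lines, and AKAP12 went from 71.7 to 746.0 CPM in SW620.

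The glycolysis and hypoxia list had the smallest camera adjusted p in SW620. Of 32 genes 27 rose and 1 fell (28 and 1 adjusted over the list alone), among them the glucose transporter SLC2A3 (log2 fold change 2.60 ± 0.14, SE), the oxygen sensor EGLN3 (2.30 ± 0.15) and the enolase ENO2 (1.90 ± 0.14), and the carbonic anhydrase CA12, named after its values were seen, fell (-2.52 ± 0.36). The median was 1.10 with a camera adjusted p of 1.95e-54, and 0.0234 with an estimated correlation. Of 21 histone genes 14 rose and none fell (16 and 0 adjusted over the list alone), with H2BC11, H2AC6 (1.93 ± 0.14) and H1-2 (2.43 ± 0.19) among them. Their median was 1.36 and their adjusted p 2.05e-25, and 0.0234 with an estimated correlation. Of 30 G2/M and mitosis genes 28 rose and none fell (29 and 0 adjusted over the list alone), including the phosphatase CDC25C (1.34 ± 0.15) and the checkpoint kinase BUB1 (0.94 ± 0.12). Their median was 0.66 and their adjusted p 1.49e-23, and 0.0234 with an estimated correlation. Of 21 NF-kB and inflammatory cytokine genes 11 rose and 1 fell (12 and 2 adjusted over the list alone), including NFKB2 (1.44 ± 0.14) and the chemokines CXCL8 (1.50 ± 0.15) and CCL20 (1.83 ± 0.24). The NF-kB median was 0.52 and the adjusted p 1.24e-08, and 0.0234 with an estimated correlation. The faller, named after its values were seen, was the adhesion receptor ICAM1 (-0.71 ± 0.23), which lost its call without any 1 of the 4 SW620 libraries (adjusted p from 0.144 to 0.265). Of 23 mesenchymal and invasion genes 10 rose and 2 fell (10 and 3 adjusted over the list alone), with the integrin ITGA5 (1.45 ± 0.12) and vimentin, VIM (1.43 ± 0.15), up and the matricellular CCN1 (-1.03 ± 0.14) and CCN2 (-1.19 ± 0.27) down. The median was 0.37 and the adjusted p 4.34e-07, and 0.0370 with an estimated correlation. CCN1 and CCN2 were named after their values were seen, and CCN2 lost its call without SW620 control replicate 2 (0.0900) or SW620 caffeine replicate 2 (0.0727). These 5 lists kept their calls with an estimated correlation and when any 1 library was left out.

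Of 24 epithelial adhesion genes in SW620, a list that lost its call with an estimated correlation (adjusted p = 0.0562), 8 rose and none fell (9 and 1 adjusted over the list alone), including E-cadherin, CDH1 (log2 fold change 0.97 ± 0.13, SE), the integrin ITGB4 (0.99 ± 0.12) and plakoglobin, JUP (0.83 ± 0.11). The median was 0.26 and the camera adjusted p 0.000120 with the preset correlation. Of 22 unfolded protein response genes 10 rose and none fell (12 and 0 adjusted over the list alone), with the COPII coat gene SEC24D (1.22 ± 0.14) and the chaperone HSPA5 (0.89 ± 0.12) up. Their median was 0.40 and their adjusted p 8.43e-06, and 0.0758 with an estimated correlation. Of 22 cAMP and CREB targets 5 rose and 1 fell (6 and 1 adjusted over the list alone), including AREG (2.32 ± 0.18), PER1 (1.50 ± 0.15) and NR4A1 (1.10 ± 0.15), which are a growth factor, a clock gene and a nuclear receptor. The median was 0.11 and the adjusted p 0.00422, and 0.130 with an estimated correlation. Named after their values were seen, FOS (0.34 ± 0.11) and the phosphodiesterase PDE4D (0.54 ± 0.16) were the other risers and PDE3B (-0.61 ± 0.17) the faller. FOS lost its call without any 1 of the 4 SW620 libraries (adjusted p from 0.150 to 0.341), and PDE4D and PDE3B without SW620 control replicate 1 (0.243 and 0.158) or 2 (0.106 and 0.133), PDE4D without SW620 caffeine replicate 2 (0.391) and PDE3B without SW620 caffeine replicate 1 (0.218).

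The remaining called lists were lower in SW620, and each lost its call with an estimated correlation. Of 30 ATF4 and amino acid response genes 9 fell and 1 rose (10 and 2 adjusted over the list alone), including NUPR1, the glycine transporter SLC6A9 (log2 fold change -1.10 ± 0.13, SE) and CHAC1 (-0.78 ± 0.14). The riser, named after its values were seen, was the transcription factor DDIT3 (0.49 ± 0.16). It lost its call without SW620 control replicate 1 or 2 or SW620 caffeine replicate 1 (adjusted p = 0.235, 0.209 and 0.333). The median was -0.20 and the camera adjusted p 0.000663, and 0.519 with an estimated correlation. Of 34 DNA replication and S phase genes 7 fell and 1 rose (11 and 1 adjusted over the list alone), with the clamp protein PCNA (-0.88 ± 0.13) as an example. The median was -0.26 and the adjusted p 0.000736, and 0.519 with an estimated correlation. The riser, RRM2 (0.52 ± 0.12), and DKK1, the riser among the Wnt targets, were named after their values were seen, and each lost its call without any 1 of the 4 SW620 libraries (0.0501 to 0.150 for RRM2, 0.0571 to 0.173 for DKK1). Of 23 Wnt targets 7 fell and 1 rose, also adjusted over the list alone, including the negative regulator APCDD1 (-1.49 ± 0.13) and the stem cell markers LGR5 (-1.27 ± 0.13) and ASCL2 (-1.04 ± 0.17), and DKK1 rose (1.33 ± 0.35). The median was -0.09 and the adjusted p 0.00119, and 0.111 with an estimated correlation. Of 57 cytosolic ribosomal protein genes 1 fell, RPS23 (-0.73 ± 0.13), also adjusted over the list alone, at a median of -0.26 and adjusted p = 0.000120, and 0.692 with an estimated correlation. Without SW620 caffeine replicate 2 the ribosomal list's adjusted p was 0.0646. Of 23 immunoproteasome assembly and MHC class I genes 4 fell and none rose, also adjusted over the list alone, including HLA-B (-0.90 ± 0.13), PSMB9 and B2M (-0.47 ± 0.13). The median was -0.15 and the adjusted p 0.0241, and 0.506 with an estimated correlation. Without SW620 caffeine replicate 2 that list's adjusted p was 0.0629, and B2M had 0.0969, 0.233 and 0.228 without SW620 control replicate 1, SW620 control replicate 2 and SW620 caffeine replicate 2. NLRC5, an activator of MHC class I genes (-0.44 ± 0.14), was the other faller and lost its call without any 1 of the 4 SW620 libraries (0.0581 to 0.320).

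**Figure D3:**
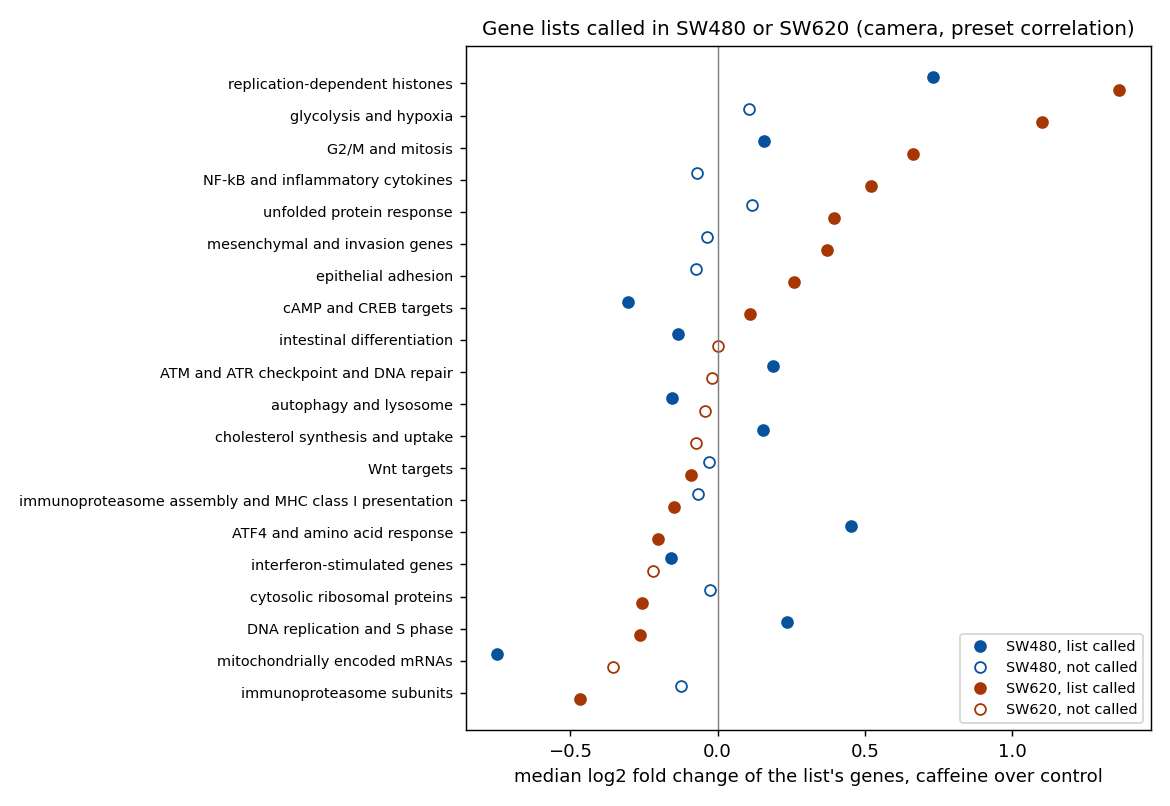
Median log2 fold change (caffeine over control) of the genes of each of 20 fixed lists that were called in SW480 or SW620; filled points are lists called by camera with the preset correlation and open points were not called. ATF4 and amino acid response and DNA replication and S phase lay above 0 in SW480 and below 0 in SW620, and histones lay above 0 in both.

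The caffeine responses of the lines were then compared with each other. The ATF4 and amino acid genes and the S phase genes stood on opposite sides of 0 in the 2 lines, and the glycolytic, mitotic, adhesion and inflammatory lists responded more positively in SW620. None of these 6 list differences kept its call with an estimated correlation (adjusted p from 0.0748 to 0.222). CHAC1 differed by a log2 value of -2.16 ± 0.22 (SE, SW620 minus SW480), INHBE by -2.20 ± 0.22 and CPLX2 by -2.63 ± 0.22. Each was higher with caffeine in SW480 and lower in SW620, where INHBE lost its call without SW620 control replicate 1 or 2 or SW620 caffeine replicate 1 (adjusted p = 0.0543, 0.136 and 0.122). LBH differed by 4.24 ± 0.23, EMP1 by 3.93 ± 0.26, NDRG1 by 3.56 ± 0.21 and AKAP12 by 3.55 ± 0.20, each called in SW620 and not in SW480. TNFSF10 differed by 2.37 ± 0.29, with a fall in SW480 and a log2 fold change of 0.27 in SW620.

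The edgeR test of the difference called 1185 of 17671 genes, with 749 responding more positively in SW620 and 436 more negatively. The adjusted p values were 2.01e-08 for LBH, 1.56e-07 for EMP1, 2.78e-08 for NDRG1, 2.01e-08 for AKAP12, 1.90e-05 for INHBE, 2.27e-05 for CHAC1, 4.15e-06 for CPLX2 and 0.000127 for TNFSF10. The other 7 of the 10 largest differences, COL13A1, KCNJ10, INTS4P1, EDN3, FGFBP1, TFF3 and CA6, each had a group with 3 counts or fewer in 1 line, and each lost its call without at least 1 library. Of these, 6 did so without SW620 control replicate 1, without SW620 control replicate 2 or without SW620 caffeine replicate 2 (adjusted p up to 0.149, 0.128 and 0.145), 5 without SW620 caffeine replicate 1 (up to 0.0949), and 4 without SW480 caffeine replicate 2 (up to 0.398). FGFBP1 and CA6 did so without SW480 control replicate 1 (0.131 to 0.146), FGFBP1 without SW480 caffeine replicate 1 (0.141) and TFF3 without SW480 control replicate 2 (0.111). INTS4P1 fell in SW620, and in SW480 it had 5 counts with caffeine and 0 without. FGFBP1 in SW480 had a ratio of 6.96 (counting interval 1.64 to 62.4) and CA6 a ratio of 3.77 (1.04 to 20.6). By edgeR, INTS4P1, FGFBP1 and CA6 were not called in SW480 (adjusted p = 0.164, 0.106 and 0.171). The count of differing genes ran from 421 to 2156 over the 8 fits that left out 1 library.

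By camera, 14 lists differed between the lines, and none of them kept its call with an estimated correlation (adjusted p from 0.0748 to 0.657). Glycolysis and hypoxia (median difference 0.81, adjusted p = 8.53e-36, 19 of 32 genes up), G2/M and mitosis (0.50, 2.37e-10, 8 of 30 up) and mesenchymal and invasion genes (0.63, 1.45e-06, 8 of 23 up) had an adjusted p of 0.0748 each with an estimated correlation. So did epithelial adhesion (0.47, 1.26e-05, 6 of 24 up) and NF-kB and inflammatory cytokines (0.56, 0.000164, 6 of 21 up). ATF4 and amino acid response (-0.64, 4.39e-16, 14 of 30 down) and DNA replication and S phase (-0.48, 4.43e-10, 7 of 34 down) had 0.133 and 0.222. The counts adjusted over the list alone were 23 up and 1 down for glycolysis, 18 up for G2/M, 11 up and 2 down for mesenchymal genes, 10 up for adhesion, 8 up and 1 down for NF-kB, 20 down and 1 up for ATF4 and 15 down for S phase. Across all 17671 genes, which are not independent replicates, the responses of the lines had a Pearson correlation of 0.0594 and a Spearman correlation of 0.0661.

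**Figure D4:**
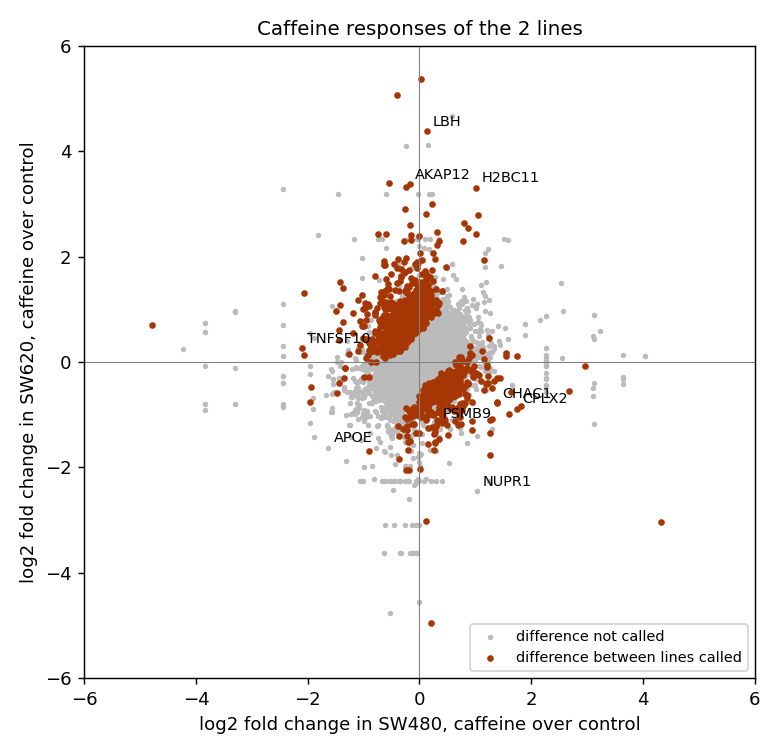
Log2 fold change with caffeine in SW480 (horizontal) against SW620 (vertical) for 13121 genes with a mean log2 CPM of at least 1; 1133 genes whose response differed between the lines by the interaction test are coloured. LBH and AKAP12 lie high on the vertical axis near 0 on the horizontal one, and CHAC1 and CPLX2 lie right of and below 0.

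A shared response was sought with all 8 libraries, 4 with and 4 without caffeine. Histone and mitotic genes were higher with caffeine over both lines, and APOE was lower. Both lists lost their calls with an estimated correlation (adjusted p = 0.448 each) and by fry (0.104 each). The mitotic list's median was 0.16 in SW480 and 0.66 in SW620, and the histone list's 0.73 and 1.36. By camera both responses were more positive in SW620 (median difference 0.50 and 0.77), calls that were lost with an estimated correlation. APOE had a log2 fold change of -1.63 ± 0.15 (SE, adjusted p = 8.02e-05), H2AC6 of 1.58 ± 0.15 and H2BC12 of 1.51 ± 0.13 (each 8.02e-05), and RAET1L, a ligand of the NK cell receptor NKG2D, of 1.84 ± 0.28 (0.00454). The glycosyltransferase GCNT3 fell (-1.75 ± 0.23, 0.00141), as did the RING finger gene TRIM54 (-1.61 ± 0.24, 0.00332). None of the immunosubunits was called, with PSMB8 at -0.35 (adjusted p = 0.156) and PSMB9 at -0.35 (0.465). PSMB8 passed the threshold without SW480 control replicate 1 (0.0336) and PSMB9 with the average of the lines (0.0363).

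Over both lines edgeR called 594 genes, 297 higher and 297 lower, of which 197 changed by a log2 value above 1 in size. In the direct overlap, 43 genes rose in both lines, against 23.9 expected if the calls were independent (Fisher's exact test, two-sided, adjusted p = 0.000295), and 59 fell in both, against 21.3 (adjusted p = 3.15e-12). A rise in SW480 with a fall in SW620 was seen for 24 genes, against 18.4 (0.181), and the reverse for 40, against 27.6 (0.0273). The odds ratios were 1.96 and 3.26 for the same direction and 1.33 and 1.52 for opposite directions. Genes are not independent replicates, and both contrasts came from 1 fit that shares the spread of each gene. Some overlap would thus arise in any direction, and these p values do not measure a shared response. AREG and CXCL8 rested on SW620: in SW480 their ratios were 3.19 (counting interval 0.843 to 17.8) and 6.96 (0.933 to 309). The count of calls was 1663 with the average of the lines, 1266 with no filter on low counts, 95 with the replicate number as a block and 137 without SW620 caffeine replicate 1, the lowest of the fits that left out 1 library.

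Of the lists, 8 were called over both lines and none kept its call with an estimated correlation. Only histones and G2/M and mitosis were also called in each line on its own. Glycolysis and hypoxia, the unfolded protein response and NF-kB were called in SW620 and not in SW480. Their responses were more positive in SW620 (median difference 0.81, 0.28 and 0.56), so that their calls here do not show a shared response. Histones (9 of 21 up, 15 adjusted over the list alone, median 1.31, adjusted p = 9.87e-19), G2/M and mitosis (11 of 30 up, 27 adjusted over the list alone, 0.40, 2.67e-19) and glycolysis and hypoxia (8 of 32 up and 1 down, 21 and 1 adjusted over the list alone, 0.63, 9.55e-16) each had an adjusted p of 0.448 with an estimated correlation. So did the unfolded protein response (3 of 22 up, 6 adjusted over the list alone, 0.23, 3.25e-05) and immunoproteasome assembly and MHC class I genes (2 of 23 down, also adjusted over the list alone, -0.14, 0.0141). The last lost its call without SW480 control replicate 2 (0.0745). HLA-B fell over both lines (-0.64 ± 0.12, SE, adjusted p = 0.0132) and lost its call without SW620 control replicate 1 (0.0540) or SW620 caffeine replicate 1 (0.0619). Mitochondrially encoded mRNAs (median -0.60, adjusted p = 0.000543, no gene called and 1 down adjusted over the list alone), ribosomal proteins (-0.17, 0.00102, no gene called) and NF-kB and inflammatory cytokines (0.27, 0.00316, 2 of 21 up and 1 down, 4 and 1 adjusted over the list alone) had 0.767, 0.863 and 0.767 with an estimated correlation. The first lost its call without SW480 control replicate 1 (0.0577), the second without SW480 control replicate 2 (0.169) or SW620 caffeine replicate 2 (0.194), and the third without SW620 caffeine replicate 2 (0.0674). The mitochondrial share of SW480 caffeine replicate 2 was 1.63%.

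The untreated lines differed far more from each other than either did from its caffeine group. The SW620 controls were higher than the SW480 controls in epithelial adhesion and in amino acid response genes, and lower in mitotic, lysosomal and sterol genes. None of these 5 list calls was kept with an estimated correlation (adjusted p from 0.132 to 0.679). E-cadherin, CDH1, stood 7.92 log2 units higher and the splicing regulator ESRP1 5.17 units higher in SW620. The retrotransposon-derived gene PEG10 was at least 1890-fold higher, the hepatic lipase LIPC at least 1220-fold and MACC1, a regulator of MET, at least 1110-fold, each with 0 counts in the SW480 controls. PHLDB2 was at least 626-fold lower in SW620 and ACSS1, a mitochondrial acetyl-CoA synthetase, at least 392-fold lower. Among the proteasome subunits PSMB10 was higher in SW620 (0.91, adjusted p = 0.00229), and PSMB9 (-0.58, 0.00495), PSMB6 (-1.15, 1.84e-05) and PSMB5 (-0.46, 0.0344) were lower. PSMB9 lost its call without SW620 control replicate 1 (0.0590), and PSMB5 without SW620 control replicate 1 (0.257) or SW480 control replicate 2 (0.395).

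Between the controls edgeR called 11591 of 17671 genes, 5830 higher and 5761 lower in SW620, and 6889 with a log2 value above 1 in size. By camera 10 lists were called, and none kept its call with an estimated correlation (adjusted p from 0.132 to 0.727). ATF4 and amino acid response had 23 of 30 genes up and 1 down (median 1.22, adjusted p = 5.12e-09), epithelial adhesion 17 of 24 up and 3 down (1.10, 6.02e-07) and ribosomal proteins 42 of 57 up (0.74, 0.000946). Higher too were intestinal differentiation 9 of 15 up and 3 down (2.92, or 2.79 with 3 genes at their bound, 0.00274) and NF-kB 12 of 21 up and 5 down (0.87, 0.0383). G2/M and mitosis had 25 of 30 down (-1.16, 1.33e-05), autophagy and lysosome 22 of 29 down and 4 up (-0.86, 0.000365) and cholesterol synthesis and uptake 20 of 25 down and 3 up (-0.88, 0.00347). Lower too were mesenchymal and invasion genes 13 of 23 down and 6 up (-0.87, 0.0174) and heat shock response 14 of 20 down and 1 up (-0.67, 0.0191). NF-kB lost its call with no filter on low counts (0.107) and without SW480 control replicate 1 or 2 (0.0640 and 0.0617). Adjusted over the list alone the counts were 24 up for ATF4, 10 up for intestinal differentiation and 26 down for G2/M.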

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

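The tests chosen only after the result was seen were the 2 carry-over tests, the 2 S phase tests, the test for SW480 cells or reads in the SW620 caffeine libraries and the test on 18 splits.

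The results given here drew attention because the caffeine response differed between the lines by the edgeR interaction test. Among the genes named in the text 58 did so (log2, SW620 minus SW480), of which 33 were higher: COL13A1 5.46, KCNJ10 5.36, LBH 4.24, EMP1 3.93, NDRG1 3.56, AKAP12 3.55, PTPRH 3.16, SLC2A3 2.78, H2BC4 2.78, CDH1 2.46, TNFSF10 2.37, H2BC11 2.29, GRIN2B 2.22, ENO2 2.17, EGLN3 1.94, ITGA5 1.67, PER1 1.64, NR4A1 1.57, SHANK1 1.47, NFKB2 1.45, JUP 1.44, VIM 1.43, H1-2 1.42, SEC24D 1.23, IGFL2-AS1 1.20, CEACAM1 1.05, CDC25C 0.94, BUB1 0.90, MUC13 0.88, H2AC6 0.77, FOS 0.75, HSPA5 0.71 and ITGB4 0.68. The other 25 were lower: DDIT4 -0.59, TYMS -0.70, PCNA -0.96, LGR5 -0.97, SESN2 -1.23, GINS2 -1.28, APCDD1 -1.31, PSD2 -1.38, SPNS2 -1.42, PSMB9 -1.49, SLC6A9 -1.56, TXNDC5 -1.63, IDNK -1.75, ASCL2 -1.75, CTHRC1 -1.82, GPX8 -1.86, NELL2 -2.04, CHAC1 -2.16, INHBE -2.20, CPLX2 -2.63, CA6 -2.65, TFF3 -3.04, FGFBP1 -3.23, EDN3 -5.16 and INTS4P1 -7.35. For COL13A1, KCNJ10, EDN3, INTS4P1, TFF3, FGFBP1 and CA6, with 3 counts or fewer in a group, these fitted values depend on the prior count and are no bounds. With 1 library left out, 38 of the 81 differences called among all genes named by the rule or later lost their call, from 1 without SW480 control replicate 2 (0.111) to 35 without SW620 control replicate 1 (0.0526 to 0.216).

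By camera 14 lists differed between the lines, and none of them kept its call with an estimated correlation (adjusted p from 0.0748 to 0.657). The medians of 9 were positive: glycolysis and hypoxia 0.81, histones 0.77 (adjusted p = 6.25e-06), mesenchymal and invasion genes 0.63, NF-kB 0.56, G2/M and mitosis 0.50, epithelial adhesion 0.47, cAMP and CREB targets 0.43 (0.000761), unfolded protein response 0.28 (0.00691) and autophagy and lysosome 0.23 (0.00691). The others were Wnt targets -0.0075 (0.0194), ribosomal proteins -0.25 (0.00290), cholesterol synthesis -0.26 (0.0101), DNA replication and S phase -0.48 and ATF4 and amino acid response -0.64. Cholesterol lost its call without SW480 control replicate 1 (0.185) or SW480 caffeine replicate 2 (0.0619). Ribosomal proteins lost it without SW480 control replicate 1 (0.568), SW480 caffeine replicate 1 (0.180) or SW620 caffeine replicate 2 (0.210). Wnt targets did so without SW480 control replicate 2 (0.0772) or SW620 caffeine replicate 1 (0.108).

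Of the calls, 1 in SW480 (TFF3) and 2 in SW620 (NELL2 and EDN3) were in genes near the floor in that line and abundant in the other, so that reads carried over between libraries might have made them. In SW480 the pooled caffeine to control ratio of 48 genes specific to SW620 was 1.137 (95% interval 0.967 to 1.34), below the fold of at least 2.11 that the counts of TFF3 allow. In SW620 the ratio of 55 genes specific to SW480 was 0.8257 (0.728 to 0.936), against a median of 2.15 for the lowest folds that the counts of NELL2 and EDN3 allow. Both ratios were smaller changes than these bounds. The 3 genes were picked because their change was called, however, and the bounds make no allowance for that choice. A pooled ratio also does not show whether the few counts of a single gene came from its own line. The test therefore cannot decide whether carried-over reads made these calls. In all, 5 definitions of the specific genes were tried. Other CPM minimums gave 1.09 to 1.10 and 0.799 to 0.827. Genes picked on low control counts, a choice that favours a rise by regression to the mean, gave 2.11 (1.43 to 3.16), which reached the bound for TFF3, and 0.993. Carry-over stays open for these calls, and biological regulation of these genes stays open and untested.

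Histone mRNAs, most of which lack a poly-A tail, were higher as a list in both lines, and weaker poly-A selection could raise them. In SW480 5 of 21 were called, and the list lost its call with an estimated correlation (adjusted p = 0.364) and by fry (0.0563). In SW620 the 5 tested of 36 other RNAs without a poly-A tail had a median log2 fold change of -0.3204 (-0.603 to 0.485). That was below 0.682, the bound set beforehand at 0.5 of the histone median. With 5 RNAs the interval only spans their lowest and highest values and leaves out the error of each. The RNA at the median, SNORD3A, had an SE of 0.885. In SW480 the median of the 5 RNAs was 0.3851 (-0.403 to 0.785) against 0.366. Selection and a histone response therefore cannot be told apart in either line with 5 RNAs. More cells in S phase would raise the S phase list, whose mean log2 CPM per library in SW620 was lower with caffeine by -0.2405 (95% interval over libraries -0.440 to -0.0408), which argued against it. The fall of that list was not called with an estimated correlation (adjusted p = 0.519) or by fry (0.0651). In SW480 the same mean was higher with caffeine by 0.2537 (0.0540 to 0.453), as more cells in S phase would need, so that this explanation stays open there. The rise of the list was lost as a call with an estimated correlation (0.502) and by fry (0.0897). A change in histone mRNA processing stays a hypothesis that was not tested.

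SW620 had 2537 calls and SW480 636, which greater replicate spread in SW480, depth or admixed SW480 material might have produced. The covariance of fold changes between separate library pairs, to which independent noise does not add, was 2.823 times as large in SW620 (12465 genes). Its 95% interval, 2.60 to 3.07, came from resampling genes and does not measure the spread between libraries. Noise shared by the replicates of a group would add to it, and whether replicates were separate cultures was not given. With each library thinned to 15760259 reads SW620 still had 4.119 times the calls (2385 against 579). The SW480 share of the SW620 caffeine libraries was at most 0.128%, from 55 genes specific to SW480 that were chosen on the SW620 controls alone, while the 456 of 1432 rising genes that were higher in SW480 would need a median of 42.4% (lower quartile 21.4%). These values argued against depth and admixture. If replicate noise was independent, they also argued against replicate spread as the whole source. A part played by spread stays open, since the biological coefficient of variation was 13.1% in SW480 and 7.02% in SW620. A difference between the lines, or in a dose, time or culture that the labels did not state, stays open and untested. For the genes called over both lines, the 18 splits of the 8 libraries with 2 of each line on each side are too few for a share under 5%. The real split, 1 of the 18, gave 594 genes and the highest other 231, which set the SW480 controls with the SW620 caffeine libraries. The bound set beforehand counted all 34 splits that could be fitted, which was wrong, since the other 16 are uneven over the lines.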

How the results depend on the processing

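The fit without mitochondrial genes was chosen after seeing the data. In fits that left out 1 library, the lone library of its group is assumed to vary like the other groups. The fall of PSMB9 in SW620 kept its call in every alternative and with any 1 library left out (-1.24 to -1.11). Of the named results, 6 lost their call with DESeq2 size factors and 575 did not, against 18 and 501 with the DESeq2 test, 22 and 433 with limma-voom, and 2 and 577 without mitochondrial genes. The second number of each pair includes results that had no call to lose. The DESeq2 test and limma-voom were run on genes and not on lists, and limma-voom was not run over both lines. With no filter on low counts 17 results lost their call, the SW480 count rose from 636 to 1073, and the count over both lines from 594 to 1266. In that fit PSMB8 in SW620 passed the threshold (-0.45, adjusted p = 0.0388), and PSMB7 over both lines turned sign (0.006087). Separate fits of each line ended 13 calls and gave 4617 genes in SW620 in place of 2537, with PSMB8 at -0.46 (0.00398). The SW480 count of its separate fit is not reported here. The coefficient of variation over all libraries, 10.5%, lay below that of the SW480 libraries (13.1%) and above that of the SW620 libraries (7.02%). With the replicate number as a block 50 calls ended, the count over both lines was 95, and PSMB8 in SW620 was -0.47 (0.0303). The average of the lines gave 1663 genes over both lines and turned INTS4P1 (0.65) and LRP2 (0.87), which rest on few counts. The cause of these changes was not tested.

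The lists depended on the assumed correlation: with an estimated one, 0 of 11 lists stayed called by camera in SW480, 5 of 14 in SW620, 0 of 14 for the difference between lines, 0 of 8 over both lines and 0 of 10 between the controls. By fry, which asks whether a list moves on balance one way, 4, 16, 16, 0 and 29 lists were called. With 1 library left out, the genes called ranged from 50 to 1367 in SW480, 787 to 3225 in SW620, 421 to 2156 for the difference, 137 to 753 over both lines and 9687 to 11763 between the controls. The lists ranged from 7 to 13, 11 to 15, 13 to 16, 7 to 11 and 9 to 11. The same fits gave PSMB8 -0.46 to 0.0486 in SW480, -0.53 to -0.41 in SW620 and -0.0381 to 0.46 between the controls, and PSMB10 -0.50 to 0.23 in SW480 and -0.47 to 0.26 for the difference. PSMB6 ran from -0.22 to 0.33 in SW480, -0.11 to 0.0529 in SW620, -0.35 to 0.19 for the difference and -0.10 to 0.12 over both lines. PSMB7 ran from -0.36 to 0.16, -0.0755 to 0.20, -0.0876 to 0.43 and -0.10 to 0.10 in the same order, and PSMB5 over both lines from -0.14 to 0.14. Without SW480 control replicate 2, PSMB8 between the controls (0.46, adjusted p = 0.0220) and the PSMB5 difference between lines (-0.76, 0.0397) passed the threshold. Of the called genes named by the rule or later, 51 of 66 in SW480, 76 of 146 in SW620, 38 of 81 for the difference, 37 of 63 over both lines and 2 of 150 between the controls lost their call without at least 1 library. Depth limits genes near the floor of 3 counts: 2 calls in SW480 and 8 in SW620 had a group at 0, and 3 and 22 a group at 1 to 3 counts.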

Other observations

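Of the lists tied to known targets of caffeine, 4 were not called by camera in either line, unlike cAMP and CREB targets in both lines and the ATM and ATR list in SW480, calls that were lost with an estimated correlation. Phosphodiesterases had a median log2 fold change of -0.32 in SW480 (adjusted p = 0.170) and 0.05 in SW620 (0.768), and adenosine receptors and handling -0.14 (0.411) and 0.09 (0.667). Calcium channels and pumps had -0.11 (0.443) and 0.03 (0.570), and aryl hydrocarbon receptor targets 0.01 (0.449) and -0.13 (0.557). Single members of each of these lists were called in SW480 or SW620, some higher and some lower, and a list median can hide such opposite changes. Among the phosphodiesterases, for example, PDE4D was called higher and PDE3B lower in SW620, calls that were lost in some fits without 1 library. The other proteasome lists were not called in either line, with medians of 0.04 (0.620) and -0.04 (0.760) for the constitutive 20S subunits and 0.04 (0.416) and 0.04 (0.940) for the 19S and other regulators. Annotated exons of PSMA2 share 781 bases with AC010132.3 on the same strand and 1043 bases with AC010132.2 on the opposite strand. Its counts may therefore leave out shared reads and need not show the level or change of the gene. In SW620, PSMA2 was called higher (1.42, adjusted p = 0.0489, 14 counts without and 35 with caffeine) and PSMG4 lower (-0.48, 0.0421). Both lost their calls without SW620 control replicate 1 (0.341 and 0.139), SW620 control replicate 2 (0.111 and 0.295) or SW620 caffeine replicate 2 (0.175 and 0.380). PSMA2 also did so without SW620 caffeine replicate 1 (0.134) or SW480 caffeine replicate 1 or 2 (0.0514 and 0.0529) and, in alternatives, with no filter on low counts and with the replicate number as a block.

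The remaining lists called in neither line were NRF2 targets (median -0.08 in SW480, adjusted p = 0.755, and 0.13 in SW620, 0.251), p53 targets (0.02, 0.815, and 0.11, 0.526) and heat shock (-0.03, 0.755, and -0.17, 0.0940). Others were fatty acid synthesis (0.06, 0.449, and -0.13, 0.570), nuclear-encoded oxidative phosphorylation (0.07, 0.276, and -0.04, 0.771) and apoptosis regulators (-0.05, 0.411, and 0.08, 0.245). The marker lists of other cell types had few tested genes: fibroblast 5 (-0.08, 0.352, and 0.12, 0.194), leukocyte 9 (0.18, 0.755, and 0.00, 0.573) and endothelial 3 (-0.22, 0.755, and 0.67, 0.254). A value that missed the threshold does not show that a list did not change.

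Because SW480 and SW620 come from 1 patient, the hypothesis was tested that caffeine moved SW620 towards the SW480 profile. With the control libraries divided so that no library entered both measures, the Pearson correlation between the SW620 response and the SW620 minus SW480 difference over 12465 genes was -0.0596 and -0.0599, and the Spearman correlation -0.0896 and -0.0877. The weaker Pearson value, -0.0596, stayed above the bound of -0.1 set beforehand, which argued against such a shift of the profile as a whole. Of 6 lists called in SW620 and between the controls, 4 had medians of opposite sign: G2/M and mitosis (0.66 with caffeine in SW620, -1.16 between the controls), ATF4 and amino acid response (-0.20 and 1.22), ribosomal proteins (-0.26 and 0.74) and mesenchymal genes (0.37 and -0.87). NF-kB (0.52 and 0.87) and epithelial adhesion (0.26 and 1.10) had the same sign. Both medians used the same SW620 control libraries with opposite sign, so that noise in these libraries alone favours opposite signs. These lists therefore cannot decide on a shift. With an estimated correlation none kept its call between the controls. In SW620 ATF4, ribosomal proteins and adhesion lost theirs (adjusted p = 0.519, 0.692 and 0.0562).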
